A study of Solanum lycopersicum with 2 samples.

How the data were processed

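DNA affinity purification sequencing (DAP-seq) recovers the fragments of a genomic DNA library that are bound by a protein outside the cell. The series lists 2 samples of tomato (Solanum lycopersicum) of the cultivar Ailsa Craig, with genomic DNA as the molecule. One is titled for the transcription factor WUSCHEL, called SlWUS in the series title, and the other is its input. The labels name the flower abscission zone and the word Halo, which is also the name of a protein tag used in this assay. There is 1 library per group, so no spread between replicates could be measured and no test between samples was possible. A peak list of the SlWUS library was used. Reads, coverage tracks and a peak list of the input library were not used here.

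The processing notes of the submitters name Bowtie2 2.2.5, a read aligner, MACS2 2.1.2, a peak caller, and ChIPseeker, a peak annotation package. The settings of each, the removal of duplicate reads and the way the input entered the peak calling are not given in the sources used here. The sequence names place the peaks on the SL4.0 build. Peak intervals and summits were used as deposited, and positions are given counted from 1. The fold enrichment of each peak is the authors' value for the pileup at the summit over the local background, in the narrowPeak layout of MACS2. The −log10 p and −log10 q values were likewise made by the authors' peak caller. The score column, as deposited, was 10 times the −log10 q cut to a whole number in 100% of peaks and was not used further. The lowest −log10 q was 1.32, which is a q of 0.0481.

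The pileup and the background behind each peak were computed from the 2 deposited values. MACS2 writes the fold as pileup plus 1 over background plus 1, and the p as the upper tail of a Poisson distribution. These relations were solved for a whole pileup. A whole number was found for 65452 of 65452 peaks at a tolerance of 0.001 on −log10 p. The largest error was 0.000117, and the next-best whole number missed by at least 0.0712. With a tail that includes the pileup itself, 0.325% of peaks gave a whole number. The pileup is therefore the number of fragments over the summit, and the background is the number expected there. The background is a scaled value and was used as the sole measure of the input. It was at its lowest value, 4.08 fragments, in 7.58% of peaks. A further 42.4% of peaks lay within 0.002 of a whole multiple of 0.437, against 0.916% by chance.

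The span of a chromosome was taken as the end of its last peak, since chromosome lengths were not used here. The first peak of each numbered chromosome started within 46481 bp of its origin. Distal zones were the outer 10% of the span at each end, and the central zone ran from 30% to 70% of it. Densities in the zones were compared as a log2 ratio per chromosome, with 0.5 added to each count of peaks, by an exact two-sided sign-flip permutation test over 12 chromosomes. The smallest p this test can give is 0.000488. Chromosomes are parts of 1 library, so this p describes positions in this library and not repeat experiments. Distances between neighbouring summits were compared with 100 draws in which each summit was placed at random within its own 100 kb window. Correlations between neighbouring peaks were tested with 1000 permutations. Exact Poisson 95% intervals of pileups cover counting error only. Whether fragments are independent molecules is not known. A summit is the highest point of its peak, so its pileup is also a selected value.

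The scripts were tested on simulated data. The pileup was recovered in 100% of 65086 simulated peaks. Densities simulated with ratios of 1 and 2 gave 0.985 and 1.99 over the 12 chromosomes. Uniform positions gave 0.990 times the short distances expected. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

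The design fixed before the data were examined also held tests of promoters, gene features, hormone gene lists, homeodomain motifs and k-mers at summits. These need the sequence and gene models of SL4.0, and they were not run. The gene table at hand belongs to another assembly, SLM_r2.1, and its positions were not used. No peak is therefore assigned to a gene, and the rule for named genes could not be applied. In its place the 15 peaks with the highest fold are named, the size that rule set for the strongest promoter peaks. The tests of zones, spacing and background, and their alternatives, were chosen after the data were seen. The zones, the classes of fold, the limit of 50-fold, the range of short distances and the limits for the background were set after several divisions had been looked at, among them a profile along the chromosomes and classes by fold and by pileup. Their p-values are not adjusted for that choice. Ties in pileup were ranked in genome order.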

Results

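The binding of SlWUS to tomato genomic DNA was measured by DAP-seq in 1 library, with 1 input library. WUSCHEL is a homeodomain transcription factor that maintains stem cells in plant meristems, and the series title places it, with the peptide CLV3, in the control of auxin and ethylene during flower abscission in low light. The question addressed here is where in the genome SlWUS-bound fragments were enriched, and how strongly. The protein meets DNA stripped of chromatin in this assay, so the peaks describe DNA that can be bound and not occupancy in the abscission zone.

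SlWUS peaks were found on all 12 tomato chromosomes. The list held 65452 peaks, of which 65446 lay on the numbered chromosomes and 6 on unplaced sequence. Together they covered 24.4 Mb. The median peak was 313 bp wide (quartiles 252 and 421 bp), and its summit lay at 49.6% of the width. Each interval had 1 summit. The median fold enrichment was 4.33 (quartiles 3.38 and 6.15). Enrichment passed 10-fold in 6043 peaks, 20-fold in 1303, 50-fold in 165 and 100-fold in 35. The median pileup at a summit was 30 fragments (quartiles 23 and 43, range 11 to 1375), over a median background of 6.11 fragments. The exact Poisson 95% interval of a pileup of 30 is 20.2 to 42.8 fragments, so the order of peaks near the median fold is not resolved by this depth. There was no replicate library, and the values below carry counting error or the spread between chromosomes only.

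Chromosomes 6, 3 and 2 carried the most peaks for their span, and chromosome 12 the fewest. Chromosome 6 had 95.03 peaks per Mb (exact Poisson 95% interval 92.3 to 97.9), chromosome 3 had 94.1 (91.8 to 96.5) and chromosome 2 had 91.5 (89.0 to 94.1). Chromosome 12 had 76.6 peaks per Mb (74.5 to 78.7), and the 12 chromosomes together had 84.7. The intervals of chromosomes 6 and 12 do not meet. They are too narrow as a measure of error, because peaks were clustered: the variance of the number of peaks over 766 full 1 Mb windows was 17.3 times the mean. Median fold hardly differed, from 4.29 on chromosome 6 to 4.38 on chromosomes 3, 5 and 12.

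Peaks were denser towards the chromosome ends, where the gene-rich euchromatin of tomato is known to lie, than in the central parts, which hold the repeat-rich pericentromeric heterochromatin. The distal zones held 20395 peaks at 132 per Mb, and the central zones 20510 peaks at 66.4 per Mb. The distal density was 1.97 times the central density (mean log2 ratio 0.98 ± 0.29, SD over 12 chromosomes). The distal zones were denser on 12 of 12 chromosomes (exact sign-flip permutation test, two-sided p = 0.000488, the smallest it can give). Chromosomes 9 and 11 had the highest ratio, 2.43 each. Chromosome 2 had the lowest, 1.15. Its first part, on the short arm side that carries the nucleolus organizer, was sparse, and its dense part lay at the other end.

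**Figure D1:**
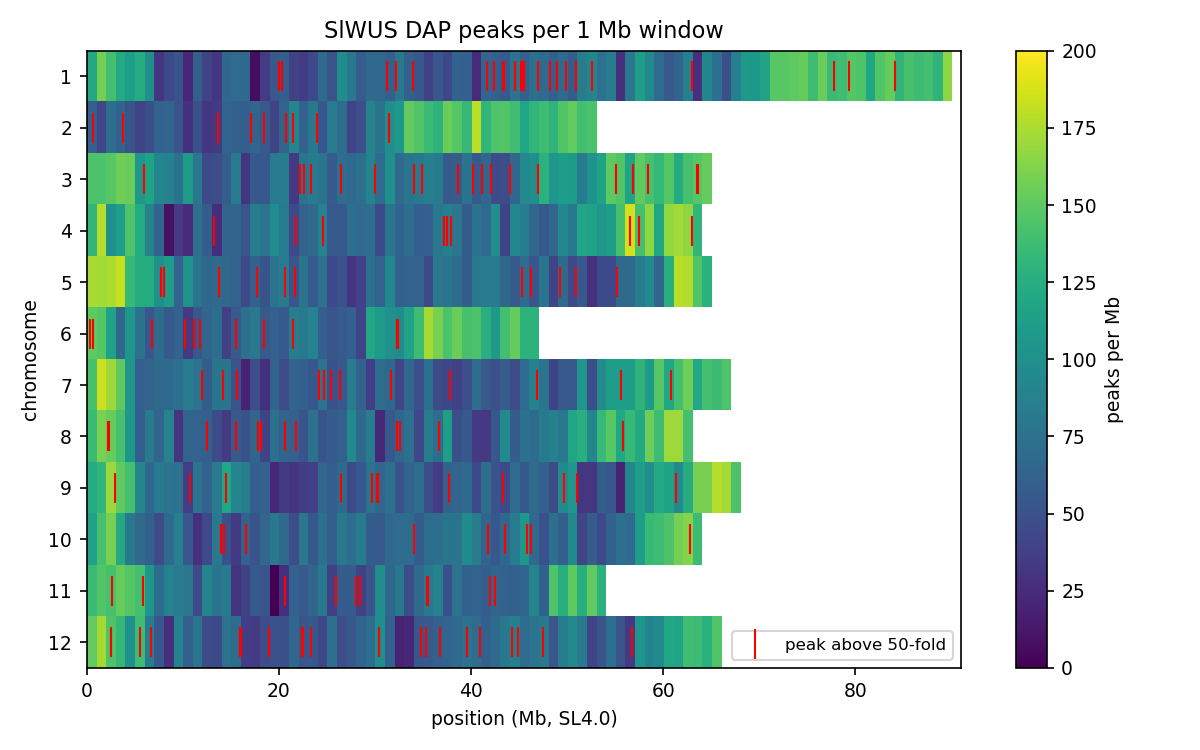
Number of SlWUS peaks in each full 1 Mb window (colour, peaks per Mb) along the 12 chromosomes (vertical axis), by position in Mb on SL4.0 (horizontal axis); red ticks mark the 165 peaks above 50-fold. Dense windows lie mostly towards chromosome ends, though the densest, with 187 peaks, is at 87.7% of the span of chromosome 4. Red ticks are mostly in the sparser central parts.

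The densest full 1 Mb window held 187 peaks and lay on chromosome 4 from 56000001 to 57000000. It was followed by chromosome 7 from 1000001 to 2000000 with 185 peaks, chromosome 5 from 3000001 to 4000000 with 183, chromosome 2 from 40000001 to 41000000 with 180, and chromosome 5 from 61000001 to 62000000 with 179. The median window held 73 peaks (quartiles 57 and 111). The window on chromosome 11 from 19000001 to 20000000 held 0 peaks, that on chromosome 1 from 17000001 to 18000000 held 7, and that on chromosome 4 from 8000001 to 9000000 held 9. The longest stretch without a peak was 1177266 bp, on chromosome 11 from 18827199 to 20004464. The next was 678396 bp, on chromosome 4 from 8445636 to 9124031. Whether reads could be placed in these stretches is not recorded in the peak list.

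The strongest peaks lacked the excess at the chromosome ends. In the 16363 peaks with the lowest fold, up to the 25th percentile, the distal density was 2.27 times the central density (log2 1.18 ± 0.40, SD, 12 chromosomes). From the 25th to the 50th percentile it was 2.09 times and from there to the 75th 1.86 times. From the 75th to the 90th percentile it was 1.83 times, from the 90th to the 95th 1.69 times, and from the 95th to the 99th 1.59 times. These 6 classes were denser in the distal zones on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488 each, 0.00057 after Benjamini-Hochberg adjustment over 7 classes). The strongest 1%, 655 peaks of at least 27.3-fold, had a ratio of 0.985 (log2 -0.02 ± 0.64) and were denser distally on 6 of 12 chromosomes (exact permutation p = 0.908). The ratio of all peaks was 2.004 times that of the strongest 1%, and higher on 11 of 12 chromosomes (exact sign-flip permutation p = 0.00195). The steady fall below the top class depended on ranking by fold. Ranked by the number of fragments at the summit, the same 7 classes gave 1.78, 2.001, 2.15, 2.09, 1.99, 1.80 and, for the top 1%, 1.13 times (exact permutation p = 0.302 for the last, denser distally on 7 of 12 chromosomes).

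Peaks above 50-fold lay mainly in the central zones. Of the 165 such peaks, 93 were central and 17 distal, which is 0.301 and 0.110 per Mb. The distal density was 0.452 times the central density (log2 -1.14 ± 0.94, SD, 12 chromosomes), and it was lower on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488). Each chromosome carried between 9 and 25 of these peaks. Counts per chromosome and zone were small: chromosome 1 had 1 distal and 20 central peaks, chromosome 7 had 0 and 7, and chromosome 10 had 1 and 3. Their median pileup was 512 fragments, their median background 6.11 and their median width 501 bp. All of these 165 peaks belong to the strongest 1%, which held 138 distal and 283 central peaks. They lower the ratio of that class, so its value near 1 does not hold for all of its peaks. A fold above 50 over the lowest background of 4.08 needs more than 192 fragments. The same peaks are therefore in the top 1% by fragments too.

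**Figure D2:**
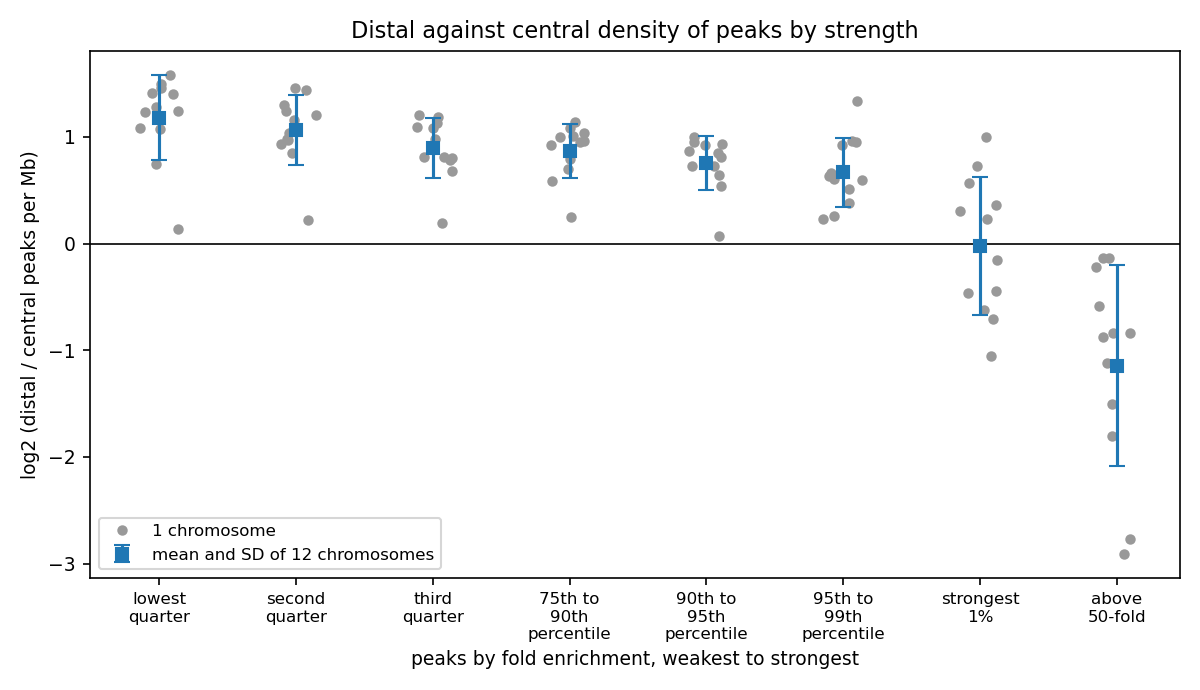
Log2 ratio of the distal to the central density of peaks (vertical axis) in classes of fold enrichment from weakest to strongest (horizontal axis). The last class, above 50-fold, is part of the strongest 1%. Grey points are single chromosomes and blue squares with bars are the mean and SD of 12 chromosomes; the mean falls from 1.18 in the lowest class to -0.02 in the strongest 1% and -1.14 above 50-fold.

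The highest enrichment, 191-fold, was at a peak on chromosome 2 from 21446161 to 21446718, with 1088 fragments at the summit (95% counting interval 1024 to 1155) over a background of 4.71. The next was 183-fold on chromosome 1 from 43274466 to 43274983, with 977 fragments. A pair of very strong peaks were neighbours on chromosome 9, one from 29682396 to 29682982 at 169-fold with 1352 fragments, and one from 29686614 to 29687169 at 131-fold with 929. Chromosome 12 held peaks of 149-fold from 30435109 to 30435723, 149-fold from 6696032 to 6696767 and 121-fold from 34824163 to 34824692. Chromosome 1 held 3 more, of 139-fold from 45275779 to 45276309, 135-fold from 49895200 to 49895709 and 127-fold from 31268333 to 31268846. The others of the 15 strongest were on chromosome 11 from 42008158 to 42008915 (139-fold), chromosome 4 from 37548754 to 37549266 (138-fold), chromosome 10 from 14253921 to 14254444 (130-fold), chromosome 2 from 3780399 to 3780929 (129-fold) and chromosome 5 from 50923320 to 50923851 (119-fold). Of these 15 peaks 10 were central, 1 was distal and 4 lay between the zones. The counting intervals of the first and second peak overlap when expressed as fold, 180 to 202 against 172 to 195. They take the background as exact, so they are too narrow as an error of the fold. The order also depends on the measure. The most fragments, 1375 over a background of 9.60, were at the chromosome 10 peak. The highest −log10 q, 2504, was at the 169-fold peak on chromosome 9. The gene, exon, intron or repeat at each of these positions was not analysed here.

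Neighbouring SlWUS peaks lay close together more often than summits placed at random. Neighbouring summits were a median of 5767 bp apart. Distances of 500 to 2000 bp occurred 15182 times, against 9151 ± 81.1 (SD of 100 draws) when summits were placed at random within 100 kb windows, which is 1.66 times as often. No draw exceeded 9330 (one-sided permutation p = 0.0099, the smallest 100 draws can give). The excess was highest from 750 to 1000 bp, at 1.86 times, and fell to 1.18 times from 2000 to 3000 bp. Distances under 500 bp are limited by the peak caller, which can join close peaks, and were not interpreted. Among distances of at least 500 bp, 23.3% were under 2000 bp, against 14.8% in the draws, a ratio of 1.58. The excess was found in both zones, at 1.58 times in the distal and 1.71 times in the central zones. Distances over 50000 bp were also too frequent, at 1.18 times. The draws could put summits where reads cannot be placed. Peaks confined to the rest of the sequence would also give too many short distances, so this excess alone does not show grouping by SlWUS.

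**Figure D3:**
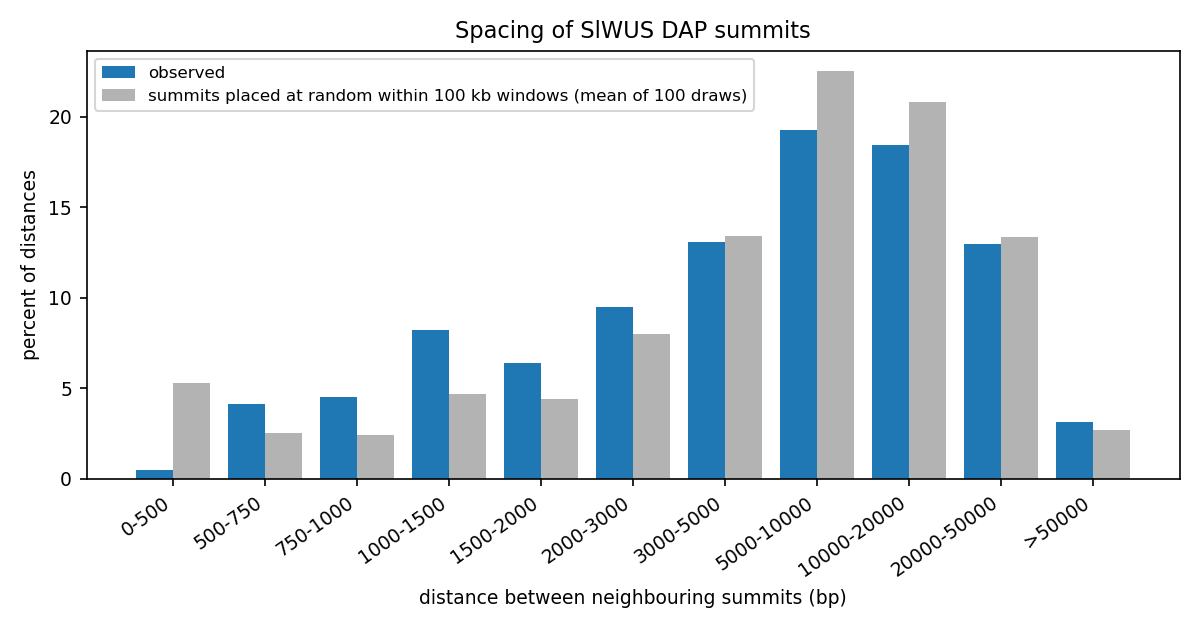
Percent of distances between neighbouring summits (vertical axis) in classes of distance in bp (horizontal axis), observed (blue) and with summits placed at random within 100 kb windows (grey, mean of 100 draws). Observed bars exceed the random ones from 500 to 3000 bp and over 50000 bp. They are below them under 500 bp, where the caller can join close peaks.

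The most crowded 20 kb windows held 12 peaks each, on chromosome 9 from 66000001 to 66020000 and on chromosome 11 from 2120001 to 2140000. A single window held up to 14 peaks in the random draws described next, so no window stood out by itself. Another 7 windows held 11 peaks, among them chromosome 1 from 72440001 to 72460000, chromosome 4 from 56540001 to 56560000 and chromosome 5 from 57560001 to 57580000. At least 10 peaks were found in 26 windows of 20 kb, against 8.52 ± 3.08 (SD) in 100 draws that kept the number of peaks in each 1 Mb (one-sided permutation p = 0.0099, the smallest 100 draws can give). These draws also did not leave out sequence where reads cannot be placed. The median fold within the 2 most crowded windows was 4.31 in both, close to that of all peaks.

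The fold of neighbouring peaks was weakly correlated over all peaks, most of which were near the median fold. Across 12497 pairs of neighbouring summits 750 to 2000 bp apart, the correlation of log2 fold was r = 0.0215 (Spearman's rho = 0.0109, permutation p = 0.018, 0.0207 after Benjamini-Hochberg adjustment over 15 relations). From 2000 to 5000 bp it was r = 0.0333 and rho = 0.0227 (permutation p = 0.000999, the smallest 1000 permutations can give, adjusted 0.00136). From 5000 to 20000 bp it was r = 0.0357 and rho = 0.0316, and from 20000 to 50000 bp r = 0.0168 and rho = 0.00829. From 750 to 20000 bp the correlation was thus not higher at shorter distances. Under 750 bp, where fragments can lie under both summits, it was r = 0.109 and rho = 0.0603. The background was more alike between neighbours, with r = 0.248 and rho = 0.211 from 750 to 2000 bp. Neighbours within one local window share part of their background by construction, so this correlation cannot be set against that of the fold. From 20000 to 50000 bp the background still had r = 0.136 and rho = 0.133 (permutation p = 0.000999, adjusted 0.00136). A default window of 10 kb does not reach that far, so sharing it does not account for all of the likeness. These are correlations across peaks of 1 library, and peaks are not independent replicates. They do not describe the strongest peaks, of which 4 neighbouring pairs above 50-fold lay within 10 kb, against a mean of 0.502 in 1000 random draws (one-sided permutation p = 0.004). Those draws did not keep the shares of the zones.

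The zones also differed in background and width. The median background was 6.37 ± 0.0433 fragments in the distal and 5.91 ± 0.0871 in the central zones (mean and SD of 12 chromosome medians), and higher distally on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488). The lowest background value was found at 3.01% ± 0.907 of distal and 9.35% ± 0.756 of central peaks (SD, 12 chromosomes). Distal peaks were wider, with a median of 323 ± 4.36 bp against 304 ± 5.85 bp, and on 11 of 12 chromosomes (exact permutation p = 0.000977). Median fold was 4.22 ± 0.0678 distally and 4.45 ± 0.0878 centrally, and lower distally on 11 of 12 chromosomes (exact permutation p = 0.000977). Median pileup was 30.5 ± 0.522 fragments distally and 29.6 ± 0.669 centrally. It was higher distally on 7 chromosomes and lower on 0 (exact sign-flip permutation p = 0.0156). Among listed peaks, the lower distal fold thus went with a higher background and not with fewer fragments. Over a higher background a peak needs more fragments to be listed, so the pileups are selected and do not describe the zones.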

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

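All tests in this part were chosen after the data were seen. The background behind each peak was not part of the comparisons of peak positions, and in 11 places several neighbouring peaks shared a background at least 2 times the median of 6.11 fragments. The clearest lay on chromosome 3 from 59213403 to 59253000, where all 13 peaks over 39.6 kb had a high background, with a median of 19.4 and a highest value of 26.6 fragments. The median fold there was 3.91, so the pileup was raised as well. A peak is listed only if it exceeds its background, so this follows from the peak calling and does not describe the stretch. On chromosome 4 from 56946617 to 57008459 the median background of 17 peaks was 12.6. On chromosome 8 from 21659863 to 21749954 it was 12.3 over 12 peaks, on chromosome 7 from 19872190 to 19931003 it was 12.4 over 7, and on chromosome 10 from 15404069 to 15470080 it was 12.2 over 8. Shorter blocks were found on chromosome 1 from 77745083 (median 12.4) and from 78823375 (13.5), on chromosome 2 from 23571149 (18.1) and from 35695878 (13.5), on chromosome 3 from 41701501 (14.6) and on chromosome 10 from 25333340 (13.1). Shuffling the background among the peaks of each chromosome gave 0 blocks in each of 1000 draws. Peaks within one local window share part of their background by construction, so the shuffles alone do not show that a block is longer than that window.

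A single site with excess reads, spread over its surroundings by the caller's local window (10 kb by default in MACS2), would keep a block within 20 kb. The spans ran from 8.79 kb, with 6 blocks under that limit, to 90.1 kb. That limit allows for 2 windows, and a default window centred on 1 narrow site would reach over 10 kb. Of the 6 shorter blocks, the one from 78823375 spanned 8.79 kb and the others 12.9 to 17.6 kb. Those wider than 10 kb go against 1 narrow site with default settings. A broader site or another setting is not excluded, so span alone does not settle the shorter blocks. The background was a whole multiple of 0.437 in all peaks of the shorter blocks from 23571149, 41701501 and 25333340. It was so in 6 of 7 peaks from 35695878, 4 of 6 from 78823375 and 1 of 6 from 77745083. Whether such values are set at the summit or by a wider window was not tested. The 5 longer blocks, of 39.6 kb or more, are wider than a single site with excess reads would reach. Several sites within the 50 kb used to link peaks would look alike, so spread sites cannot be told apart from longer stretches. Extra copies of these stretches in the Ailsa Craig DNA, or copies joined into one in the assembly, may explain the long blocks and stay open. They would raise every peak of a block, and every peak had at least 1.5 times the median background in 4 of the 5. On chromosome 10 from 15404069 the share was 87.5%, and the remaining peak had a background of 6.66, close to the median. Peaks that define a block, at 2 times the median or more, pass this limit by selection. They were 13 of 13 peaks on chromosome 3, 10 of 17 on chromosome 4 and 4 of 7 on chromosome 7. On chromosome 8 they were 7 of 12 and on chromosome 10 4 of 8. The other peaks can share local windows with them, so these shares do not speak for extra or joined copies. Reads drawn in from related sequence elsewhere would look alike, and without the sequence this stays open. No biological explanation was tested, since the design has a single genotype.

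On unplaced sequence, which held 6 peaks, 3 had a background more than 2 times the median. It was 62.0 fragments at 1517630 to 1517845, 67.2 at 5080337 to 5080595 and 17.5 at 4192488 to 4192882.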

How the results depend on the processing

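The number of peaks, fixed as a result before the data were examined, went from 65452 to 52356 at a −log10 q of at least 5. Leaving out unplaced sequence gave 65446, and keeping only the strongest summit per interval removed no peak. The other alternatives were chosen after the data were seen. The distal over central density stayed above 1 and past the threshold in 18 settings, from 1.65 with the outer 20% at each end to 2.11 without peaks at the lowest background. Leaving out each chromosome gave 1.94 to 2.07. The ratio between all peaks and the strongest ones stayed above 1 and past the threshold in 19 settings. A value above 1 means a smaller distal excess in the strongest peaks, and not that they have none. The settings are not independent, and 12 of them leave out 1 chromosome each. The ratio between all peaks and the strongest ones was lowest, 1.26, for the strongest 10% and highest, 4.37, above 50-fold. Leaving out each chromosome gave 1.84 to 2.21. The excess of short distances ranged from 1.54 with 20 kb windows to 1.76 with 1000 kb windows. The weak correlation of fold at 750 to 2000 bp (0.0215) did not pass the threshold with −log10 q in place of fold (r = 0.0134, permutation p = 0.13). The number of background blocks depended on the limit, with 33 at 1.5 times the median and 1 at 3 times. The tests of promoters, gene features, gene lists, motifs, k-mers and motif strength, and their alternatives, were not run, because the sequence and gene models of SL4.0 were not used here. No paired analysis was possible because each group has 1 library. With 1 library, the reproducibility of any single peak is unknown, and at the median pileup of 30 fragments counting error alone spans 20.2 to 42.8.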

Other observations

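All tests in this part were chosen after the data were seen. The density of peaks changed along the chromosomes on an uneven course. Pooled over 12 chromosomes, the first 5% of the span had 141 peaks per Mb, the density fell to 56.7 per Mb between 25% and 30%, and it rose to 143 per Mb in the last 5%. The density of the strongest 1% of peaks varied between 0.544 per Mb, from 75% to 80% of the span, and 1.14 per Mb in the last 5%. These extremes rest on 21 and 44 peaks, and whether the variation exceeds counting error was not tested. The density of the strongest 1% was 1.06 per Mb between 30% and 35% and 0.596 per Mb between 90% and 95%. Neighbouring peaks above 50-fold lay closer than randomly drawn peaks. Within 10 kb of each other lay 4 such pairs, against a mean of 0.502 in 1000 draws of as many peaks per chromosome from all peaks (one-sided permutation p = 0.004). Their median distance was 2251 kb, against 2821 ± 280 kb (SD) in the draws (one-sided permutation p = 0.018). The draws did not keep the shares of the zones.

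The excess of peaks near the chromosome ends may come, in part or whole, from reads lost in repeats of the central zones. The density ratio of all peaks was 2.004 times that of the strongest 1% (exact sign-flip permutation p = 0.00195), which would also follow if such loss spared the strongest peaks, and does not measure it. Loss that spares stronger peaks would make the excess fall over all classes of pileup, but it rose from 1.78 in the lowest class to 2.001 and 2.15 in the next ones before it fell to 1.13 in the top 1%. That rise goes against loss as a simple account, and does not exclude it, because the lowest pileups can pass the caller's threshold only over a low background, which was more frequent in the central zones. Weak peaks missed where coverage is low stay open too. As the whole cause, they would leave no excess past the test in peaks with a −log10 q of at least 20. The 15849 such peaks had a ratio of 1.84, above 1 on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488), which goes against that. The strongest 1% by −log10 q had a ratio of 1.06 (exact permutation p = 0.657), which does not. A q falls with coverage, so such limits do not remove its effect. The background is known at summits alone, and no biological explanation was tested, since the sequence and its methylation were not analysed here.

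The strongest peaks followed another course than the bulk. A low local background that raises the fold is argued against as the cause, since ranking by the pileup, which does not use the background, still gave a density ratio of all peaks 1.74 times that of the strongest 1% (exact permutation p = 0.00244). Copies of a repeat collapsed in the assembly would raise the input as much as the pileup. The top 1% by pileup, a ranking that favours a high background, had at least 192 fragments, 6.4 times the median of all peaks. Their median background was 6.34 (upper quartile 7.38), 1.04 times that of all peaks, which argues against collapsed copies as the whole cause of their height if the background is that of the input. A smaller part is not excluded. The sequences under these peaks, and whether they belong to a repeat family, were not analysed here, so no biological explanation was tested.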
